A study of Mus musculus with 2881 samples.

How the data were processed

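Single cells were taken from the hypothalamus of young C57BL/6N mice, either untreated or after an acute formalin stress, and each GEO sample is 1 cell. Per the labels' protocols and the series' design text, stressed animals received 4% paraformaldehyde in the left paw 6 hours before they were killed, a central column of the hypothalamus was dissected and dissociated with papain, cells were captured on Fluidigm C1 microfluidic chips, and cDNA was amplified with 21 cycles of PCR. The library method tags each cDNA molecule with a unique molecular identifier, so a count is a number of molecules and not of reads. The deposited table holds raw molecule counts for 24341 genes in 2881 cells, made by the authors from their reads. The genome build was mm10, per the submitters' processing notes, and the aligner is not given in the sources used here. Classes were assigned by the authors with BackSPIN clustering, per the labels, in 7 main classes and 63 neuron names, 1 of which, uc, marks neurons with no assigned type. The design text gives postnatal days 14 to 28, while the labels run from day 16 to day 29, and the labels were used.

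Every one of the 2881 columns was matched to its sample by title, and 0 columns of per-cell values were left unused. The counts of each cell summed to the total stated in its label in 2881 of 2881 cells, and the class, stress, sex and age lines of the table equalled the labels in all cells. No cell column was identical to another. A location number was carried by 1207 gene symbols, which marks repeated symbols, and these stayed separate. The nuclear RNA Malat1 took 6.17% of all 26060238 molecules. Cells held between 1502 and 67475 molecules, with a median of 7373 molecules and 2757 genes. No cell was removed, and no doublet caller was run, since the classes come from the authors. RNA of other cell types was followed through fixed marker lists. Cell diameters are given by the labels with no unit, and 8 values of 0 were left out.

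No label names an animal, and cells are not replicates. Cells with the same stress, sex and age labels were therefore pooled into an animal set, the smallest unit that the labels show to hold separate animals, and raw counts were summed per set and class. How many animals a set holds is not known. There were 6 control female sets, 5 control male sets and 6 stressed male sets. A chip of 83 control cells without sex or age labels entered no comparison. All stressed cells are labelled male, so stress was tested as stressed against control males and sex as control females against control males, with all 3 arms in one fit that shares the spread. A set entered the fit of a class with at least 5 cells of that class. This left 5 classes for tests of genes, and smooth muscle cells and microglia were too few.

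Genes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit with robust fitting, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Levels from the edgeR fits are CPM, counts scaled to 1e6 molecules of the genes kept by the filter, with the TMM factors. Other levels are CPM scaled to 1e6 molecules of the unit. The standard error (SE) of a log2 fold change is its size over the square root of its F statistic. Of 30 gene lists fixed before the data were examined, 22 had at least 5 tested genes in some class. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over 69 pairs of list and class. Mean log2 CPM of a list per set, with a prior count of 2, was compared by exact two-sided permutation over all assignments of the male sets that entered the class, 462 in oligodendrocytes and neurons, 252 in astrocytes and endothelial cells and 70 in ependymal cells. Shares of cells, molecules per cell and diameters were compared between sets by exact two-sided permutation tests, or by sign flips within sets for classes against neurons, which took 100000 resamples where the sets were too many to enumerate. For neuron families, defined from the authors' type names, the counts of the family and of the other classified neurons of the same set were compared in edgeR with the set as a block, with at least 3 cells per unit.

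The genes named follow a rule fixed in advance. For each comparison these were the 10 with the largest rise and the 10 with the largest fall past the threshold at a mean of at least 20 CPM, all genes past it where 10 or fewer passed, up to 5 per fixed list, and in the stress comparisons Fkbp5, Sgk1, Tsc22d3, Fos, Crh, Avp and Oxt where tested. For the interaction these were the 10 smallest p, and for neuron families up to 5 receptors and 5 transcription factors outside the class names. Members of a list past the threshold only when adjusted over the list alone, and other genes named in the stress comparisons, were chosen after their values were seen.

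No label names a lot. Chips whose numbers share their leading digits were taken as 1 lot, which is inferred from the numbers alone. Lot in this sense follows treatment closely. Only 1 lot holds both control males (2 sets, 286 cells) and stressed males (6 sets, 732 cells), and it was analysed alone. Only 1 of these control male sets held at least 5 ependymal cells there. As an alternative added after the data were seen, sets were divided by lot and lot was entered as a block. Sets that span 2 lots then give 2 units that may share animals. For 5 pairs of list and class the mean log2 CPM per unit was also compared with lot in a mixed model (nlme 3.1.168, the set as a random effect) and with age in a linear model over sets, added after the data were seen. Other alternatives were DESeq2 1.42.0, other scaling (RLE), no filter on low counts, 10 cells per unit, age as a covariate, male sets only, the chip as the unit, neurons without the uc label, each set left out in turn and, added later, control females as the reference, neurons with little oligodendrocyte RNA, neurons of the GABA family and shares among neurons with an assigned type.

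The tests were run on simulated counts with 200 changed genes per comparison before use. In simulated stress comparisons the edgeR step called 98.4% of genes changed 4-fold, 65.1% changed 2-fold and 9.84% changed 1.5-fold among 7471 genes in neurons. In oligodendrocytes it called 98.4%, 42.9% and 3.45% among 6619 genes, and of genes changed 2-fold it called 11.3% in ependymal cells (4070 genes), 12.5% in astrocytes (2184 genes) and 11.7% in endothelial cells (2387 genes). Of 50 random lists per class, 0 were called. The genes were simulated independently, so this cannot show how the list test behaves where genes of a list move together. Permutation tests used scipy 1.17.1. Gene coordinates are from the GENCODE annotation of mm10.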

Results

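Transcripts were counted in single cells of the mouse hypothalamus, 1785 from control animals and 1096 from animals 6 hours after an acute formalin stress. The authors' labels put the cells in 7 classes: 1001 oligodendrocytes, 898 neurons, 356 ependymal cells, 267 astrocytes, 240 endothelial cells, 71 vascular smooth muscle cells (vsm) and 48 microglia. Control females gave 726 cells in 6 animal sets, control males 976 cells in 5 sets and stressed males 1096 cells in 6 sets, where a set holds all cells with the same treatment, sex and age. The median cell held 8182 molecules in control females, 8210.5 in control males and 6289 in stressed males, and the summed total of a set ranged from 259260 to 4030766 molecules. Mean age was 24.2 ± 3.76 days (SD, n = 6) in control females, 22.4 ± 4.22 days (SD, n = 5) in control males and 25.8 ± 2.64 days (SD, n = 6) in stressed males. Because the labels name no animal, p-values of genes, shares and set scores measure the spread between sets. Those of camera with the preset inter-gene correlation do not measure it directly, since that correlation is fixed and not taken from the sets. A small camera p of this kind is therefore not by itself evidence across sets, and it is read with the estimated correlation and the set scores.

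The 7 classes carried the markers of their names. Plp1, the main proteolipid of myelin, stood at 55595 ± 7152 CPM (SD, n = 17 sets) in oligodendrocytes, and Snap25, a protein of synaptic vesicle release, at 1737 ± 300.0 CPM (SD, n = 17) in neurons. The astrocyte glutamate transporter gene Slc1a2 stood at 3553 ± 1034 CPM (SD, n = 14) in astrocytes, Ccdc153 at 1410 ± 304 CPM (SD, n = 12) in ependymal cells and the tight junction gene Cldn5 at 873 ± 475 CPM (SD, n = 15) in endothelial cells. Acta2, which encodes smooth muscle actin, stood at 7116 ± 3029 CPM (SD, n = 6) in vsm cells, and the complement gene C1qa at 3153 ± 2322 CPM (SD, n = 3) in microglia. Oligodendrocyte RNA was present in every class: the 12 oligodendrocyte markers summed to 95220 CPM in oligodendrocytes, 37321 in vsm cells, 29343 in astrocytes, 28674 in endothelial cells, 23526 in ependymal cells, 4550 in neurons and 4503 in microglia. In astrocytes, endothelial, ependymal and vsm cells this sum exceeded that of each class's own markers, which was 19631, 10840, 11515 and 18165 CPM. Endothelial cells also held pericyte and smooth muscle markers at 3413 CPM and fibroblast and meningeal markers at 2299 CPM. Tanycyte markers summed to 3862 CPM in ependymal cells and 2302 in astrocytes, and perivascular macrophage markers to 7968 CPM in microglia. The 12 neuron markers summed to 21792 CPM in neurons and to between 3128 and 5940 CPM in the other 6 classes. Markers of the pituitary, the choroid plexus and blood cells summed to at most 2, 130 and 317 CPM in any class.

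Neurons were the largest cells and held the most molecules. Median diameter, in the unstated unit of the labels, was 11.3 ± 0.48 (SD, n = 17 sets) in neurons, 10.8 ± 0.62 (SD, n = 15) in endothelial cells, 10.5 ± 0.80 (SD, n = 12) in ependymal cells, 10.4 ± 0.63 (SD, n = 17) in oligodendrocytes, 9.73 ± 0.51 (SD, n = 6) in vsm cells, 9.14 ± 0.72 (SD, n = 14) in astrocytes and 9.02 ± 0.16 (SD, n = 3) in microglia. Oligodendrocytes were smaller than the neurons of the same set in 17 of 17 sets (permutation test with sign flips, adjusted p = 0.000240) and astrocytes in 14 of 14 (exact, adjusted p = 0.000366). Ependymal cells (11 of 12 sets), endothelial cells (12 of 15) and vsm cells (6 of 6) also lay below neurons, with exact adjusted p of 0.00879, 0.0278 and 0.0375. The 3 microglia sets allow no exact p below 0.25. Median molecules per cell averaged 10700 ± 1631 (SD, n = 17) in neurons, 7892 ± 2070 (SD, n = 17) in oligodendrocytes, 6278 ± 1949 (SD, n = 12) in ependymal cells, 5482 ± 1941 (SD, n = 15) in endothelial cells and 3824 ± 1185 (SD, n = 14) in astrocytes. On the log2 scale these 4 classes lay below neurons by −0.46, −0.90, −1.02 and −1.52, with permutation adjusted p between 0.000244 and 0.000732.

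Stress and neurons. The stress comparison asks which transcripts differ between stressed and control males within a class. In neurons the immediate early genes, which are switched on quickly by neuronal activity, fell in stressed males: all 17 tested members had a negative log2 fold change, with a mean of −0.85 and a median of −0.71 (camera, adjusted p = 3.26e-15, and adjusted p = 0.0389 with an estimated correlation). Adjusted over the list alone, 6 members fell. Arc, a regulator of synaptic receptors (chromosome 15, 74669083 to 74672570, mm10), stood at 8.64 ± 3.68 CPM (SD, n = 6) in stressed and 46.4 ± 28.1 CPM (SD, n = 5) in control males, a log2 fold change of −2.24 (SE 0.45). Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477273), stood at 231 ± 50.8 and 619 ± 238 CPM, a log2 fold change of −1.41 (SE 0.32). The activity-dependent transcription factor gene Npas4 had a log2 fold change of −2.06, Fosb −1.64, Btg2 −1.12 and Ier3 −0.73. Per set, the mean log2 CPM of the list was lower in 6 of 6 stressed sets than the mean of control males (difference −0.85, exact permutation p = 0.0130, adjusted p = 0.456 over the 69 pairs). With 6 against 5 sets the smallest exact p is 0.00433, so 1 pair alone could not pass that adjustment.

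Glucocorticoid-responsive genes rose in neurons of stressed males, with a mean log2 fold change of 0.42 and 8 of 11 members positive (camera, adjusted p = 0.000856). That call was lost with an estimated correlation (adjusted p = 0.457). Adjusted over the list alone 3 members rose: the metallothionein genes Mt2 (1.36, SE 0.30) and Mt1 (1.26, SE 0.38), which bind zinc and copper, and Fkbp5 (1.04, SE 0.33), a chaperone of the glucocorticoid receptor that stood at 36.1 ± 2.82 CPM (SD, n = 6) in stressed and 17.4 ± 10.6 CPM (SD, n = 5) in control males. The log2 fold change was 0.64 (SE 0.31) for Sgk1, a kinase gene, and 0.33 (SE 0.25) for Tsc22d3, an anti-inflammatory leucine zipper gene. Among stress axis genes Vgf, a secreted neuropeptide precursor, fell by 1.25 (SE 0.30) when adjusted over its list alone, and the releasing hormone gene Crh was at −1.21 (SE 1.48). The peptide hormone genes Avp (−0.18, SE 1.53) and Oxt (1.03, SE 1.70) varied widely between sets. Genes of fast transmitters and monoamines had a mean of −0.26 (camera, adjusted p = 0.0101, and adjusted p = 0.457 with an estimated correlation, 0.0750 with chip lot as a block and 0.127 with age). One of them, the GABA-synthesis gene Gad2, fell when adjusted over the list alone (−0.82, SE 0.17), while Gad1 (−0.73) and the vesicular GABA transporter gene Slc32a1 (−0.66) did not pass. Neurons of the GABA family made up 14.9 ± 7.76% (SD, n = 6) of the neurons of stressed and 26.4 ± 6.30% (SD, n = 5) of control males (exact permutation, p = 0.0346, adjusted p = 0.104). Neurons named for other peptides or genes made up 16.1 ± 5.98% of the neurons of stressed and 27.8 ± 5.01% of control males (adjusted p = 0.0390 by exact permutation), and neurons with no assigned type 21.8 ± 6.37% and 10.8 ± 4.28% (adjusted p = 0.0584 by exact permutation). Among neurons with an assigned type alone the shares were 20.2 ± 6.45% and 31.1 ± 5.63% for other peptides or genes and 18.5 ± 8.69% and 29.7 ± 7.77% for the GABA family, and neither passed (exact permutation, adjusted p = 0.242 each). These comparisons of neuron shares were added after the data were seen. Cholesterol synthesis genes had a mean of 0.20 in neurons, with 15 of 16 positive (adjusted p = 0.0239, and 0.550 with an estimated correlation), and 0.0844 with chip lot as a block (adjusted p = 0.691).

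Oligodendrocyte markers moved with these groups. In neurons all 12 had a positive log2 fold change in stressed males, with a mean of 1.25 (camera, adjusted p = 1.02e-05, and adjusted p = 0.550 with an estimated correlation), and 0 passed one by one over the list alone. Mobp, a myelin gene, was at 1.91 (SE 0.69) and Cnp at 1.24 (SE 0.50). The list score was higher in 6 of 6 stressed sets than the control male mean (difference 1.24, exact permutation p = 0.0390, adjusted p = 0.456). The arms overlapped: the control male set of day 23 (7.88) lay above the stressed sets of days 27, 28 and 29 (7.19, 7.56 and 7.33). No single gene passed in neurons: edgeR called 0 of 7722 genes over all genes tested, with 519 at an unadjusted p below 0.05 and an adjusted p of 0.0988 for Arc and Gad2. DESeq2 called 10 genes, edgeR 83 with age as a covariate and 18 with male sets only.

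Because chip lot follows treatment, each list was also computed within the 1 lot that holds both kinds of male. Immediate early genes in neurons had a mean of −0.50 there and −0.65 with chip lot as a block. For glucocorticoid-responsive genes these values were 0.62 and 0.54 in neurons, 0.43 and 0.26 in oligodendrocytes, and 0.79 and 0.86 in astrocytes. Oligodendrocyte markers in neurons were at 1.20 and 0.93. In neurons of the GABA family alone the immediate early genes had a mean of −0.13 (adjusted p = 0.747).

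**Figure D1:**
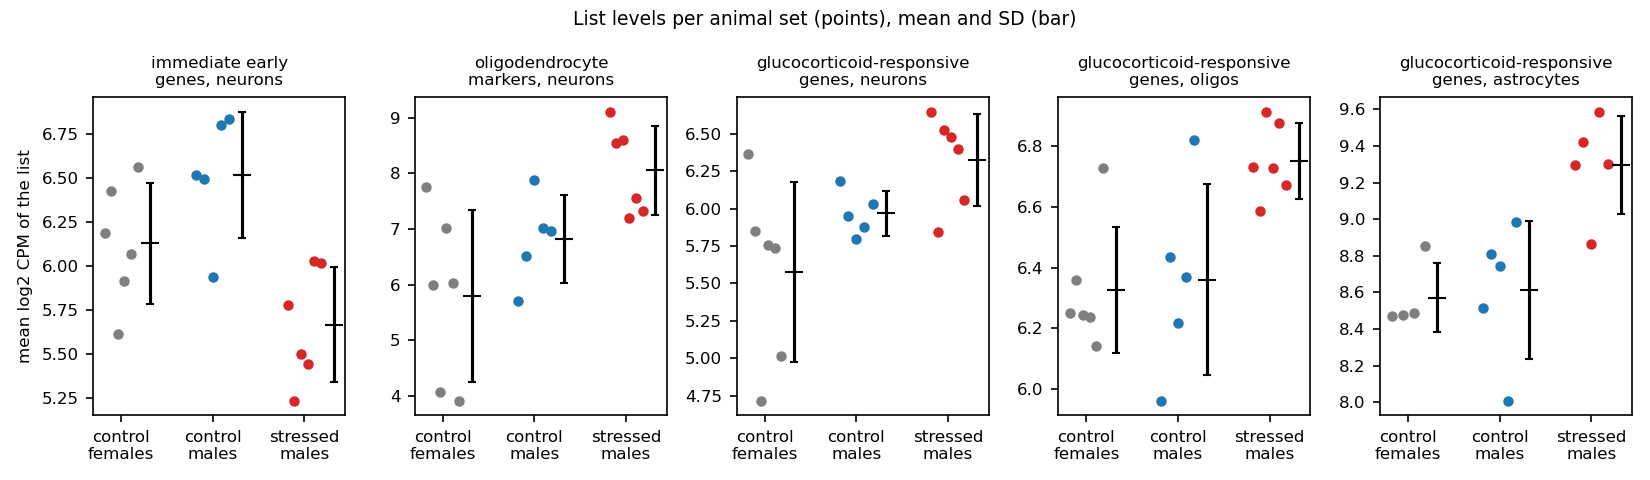
Mean log2 CPM of 5 pairs of gene list and class (vertical axes, 1 panel each) in control females, control males and stressed males. Points are animal sets, and the bar beside them is the mean with its SD. Immediate early genes in neurons lay between 5.23 and 6.03 in stressed and between 5.94 and 6.84 in control males, and glucocorticoid-responsive genes in oligodendrocytes between 6.59 and 6.91 and between 5.96 and 6.82.

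Stress and oligodendrocytes. Glucocorticoid-responsive genes had a mean log2 fold change of 0.38 and a median of 0.16 in oligodendrocytes of stressed males, with 11 of 15 positive (camera, adjusted p = 0.00145, and adjusted p = 0.298 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a (chromosome 17, 29090976 to 29100727) rose when adjusted over the list alone, from 5.51 ± 5.31 CPM (SD, n = 5) in control to 24.4 ± 6.61 CPM (SD, n = 6) in stressed males. Sgk1 was at 193 ± 61.1 against 95.5 ± 79.1 CPM (log2 fold change 0.93, SE 0.48) and Tsc22d3 at 235 ± 59.8 against 169 ± 12.6 CPM (0.47, SE 0.19). The list score was above the control male mean in 6 of 6 stressed sets (exact permutation p = 0.0216, adjusted p = 0.456). The arms overlapped: the control male set of day 27 (6.82) lay above the stressed sets of days 22, 24, 27 and 29 (6.73, 6.59, 6.73 and 6.67). Cholesterol synthesis genes, which supply the myelin lipid, had a mean of −0.20 with 15 of 18 negative (adjusted p = 0.00145, and 0.550 with an estimated correlation) but −0.0587 with age as a covariate (adjusted p = 0.348), among them Cyp51 at −0.56 (SE 0.20) and Sqle at −0.41 (SE 0.18). Nuclear genes of oxidative phosphorylation had a mean of −0.16 with 27 of 33 negative (adjusted p = 0.000856, and 0.564 with an estimated correlation), and −0.0992 with age (adjusted p = 0.0753). Immediate early genes were at −0.48 (adjusted p = 0.0199, and 0.703 with an estimated correlation) and at 0.16 against control females. Of these only Npas4 fell over the list alone (−2.48, SE 0.71), and Fos was at −0.77 (SE 0.35). The 8 tested stress axis genes were all negative (mean −0.67, adjusted p = 0.0239, and 0.494 with an estimated correlation). Most of that list encodes neuropeptides and secretory granule proteins, and Avp had the lowest value at −2.65 (SE 1.27). The list stood at −0.11 with chip lot as a block (adjusted p = 0.793), −0.47 with age (0.333) and −0.34 against control females (0.235), and within the shared lot at 0.20, with Avp at 1.97. Oxt was at −0.26 (SE 2.13). edgeR called 0 of 7073 genes (429 at an unadjusted p below 0.05) and DESeq2 0. With age as a covariate the glucocorticoid-responsive list stood at 0.28 (adjusted p = 0.0715), and its call also ended with chip lot as a block (adjusted p = 0.0627). Without the stressed set of day 25 or of day 28 it stood at 0.23 or 0.24.

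Stress in ependymal cells, astrocytes and endothelial cells. In ependymal cells, which line the third ventricle, all 10 tested neuron markers were negative in stressed males (mean −1.65, adjusted p = 9.28e-05, and 0.550 with an estimated correlation). The mean was −0.52 with chip lot as a block (adjusted p = 0.0571), −0.69 with age (0.0477) and −1.02 against control females (0.305), and the mean log2 CPM was 7.26 in stressed males, 7.30 in control females and 9.20 in control males. All 12 oligodendrocyte markers were positive (mean 1.45, adjusted p = 0.000303, and 0.564 with an estimated correlation), and at 0.70 with the chip as the unit (adjusted p = 0.142). Their score was above the control male mean in 3 of 4 stressed sets (difference 1.01, exact permutation p = 0.371). Within the shared lot they were at 4.80, but only 1 control male set had enough ependymal cells there. The cells' own markers were at 0.47 (adjusted p = 0.00716, and 0.676 with an estimated correlation) but at 0.0958 with chip lot as a block (adjusted p = 0.706) and oxidative phosphorylation genes at −0.32 (adjusted p = 0.0165, and 0.736 with an estimated correlation). Tsc22d3 rose when adjusted over the list alone, from 147 ± 58.4 to 372 ± 126 CPM (SD, n = 4 each, log2 fold change 1.30, SE 0.37), and Fos was at −1.55 (SE 0.61). Glucocorticoid-responsive genes were at 0.24 with 8 of 10 positive (adjusted p = 0.0816). In astrocytes all 8 tested glucocorticoid-responsive genes were positive (mean 0.60, adjusted p = 0.000856, and 0.153 with an estimated correlation), with Tsc22d3 at 0.95 (SE 0.39) and Mt2 at 0.85 (SE 0.35). The score was above the control male mean in 5 of 5 stressed sets (exact permutation p = 0.0159, adjusted p = 0.456). The control male set of day 27 (8.99) lay above the stressed set of day 27 (8.87). Gfap, the astrocyte intermediate filament gene, rose when adjusted over its list alone (1.87, SE 0.49), while Fos was at −0.50 (SE 0.68) and Avp at −1.80 (SE 1.88). Oxt was at 5.67 (SE 1.86), with most of its level in 2 of the 5 stressed sets. Oxidative phosphorylation genes in astrocytes were at −0.19 (adjusted p = 0.00251, and 0.550 with an estimated correlation) but at 0.33 within the shared lot. In endothelial cells immediate early genes were at −0.34 with 15 of 19 negative (adjusted p = 0.000856, and 0.564 with an estimated correlation) and at 0.16 with chip lot as a block. Cholesterol synthesis genes there were at −0.42 with 9 of 10 negative (adjusted p = 0.0239, and 0.564 with an estimated correlation) and at −0.24 with age (adjusted p = 0.328). Glucocorticoid-responsive genes were at −0.11 with 8 of 12 negative (adjusted p = 0.503). Sgk1 was at −0.75 (SE 0.46), Tsc22d3 at −0.12 (SE 0.39), Fos at −0.59 (SE 0.34) and Avp at 3.63 (SE 1.87) in endothelial cells. edgeR called 0 of 4516 genes in ependymal cells (454 at an unadjusted p below 0.05, 1 by DESeq2), 0 of 2534 in astrocytes (104, and 0 by DESeq2) and 0 of 2681 in endothelial cells (111, and 1 by DESeq2).

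Over all classes 18 of the 69 pairs of list and class passed with the preset correlation and 1, the immediate early genes in neurons, with an estimated one. Whether a stress response differed between classes was tested by the interaction of class and stress in males. Arc passed (edgeR, adjusted p = 0.0427), with a log2 fold change higher than that in neurons by 1.75 in oligodendrocytes and 2.56 in ependymal cells. In astrocytes and endothelial cells Arc was too rare to be tested within the class, with 14 and 41 molecules over all male sets, and most of these sets held none. The test uses all 5 classes. The number of genes past the threshold was 0 when any of 8 of the 11 male sets was left out. The next genes by p were Abr (adjusted p = 0.0865), Rab3c (0.0871), Sall1 (0.134), Nap1l5, 6330403K07Rik, Atp6v1g2, Cdkn1a and Disp2 (0.151 each) and a Dynlt1c entry (0.153), none of which passed. With RLE scaling 0 genes passed.

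**Figure D2:**
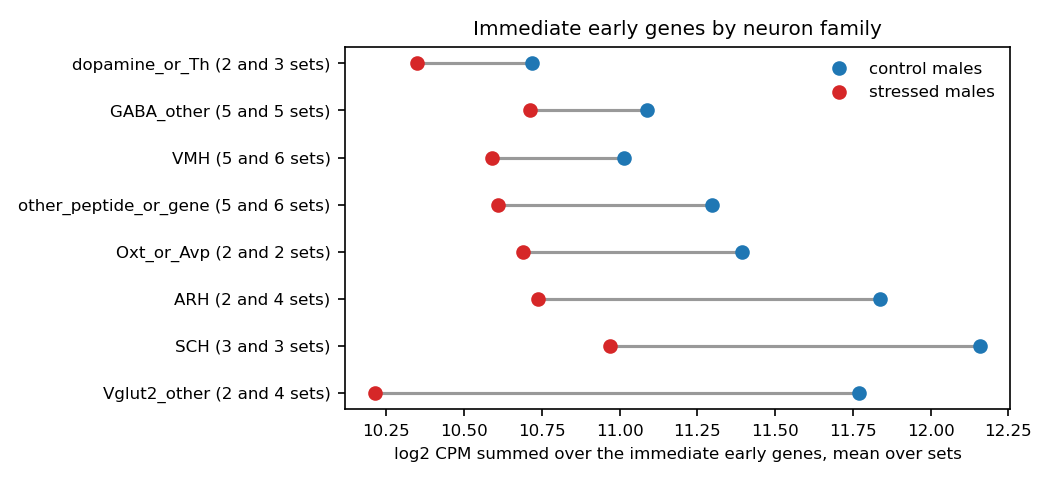
Log2 CPM summed over the immediate early genes (horizontal axis) in 8 families of neuron types (vertical axis, with the number of control and stressed male sets). Blue points are means over control male sets and red points means over stressed male sets, and all 8 families lay lower in stressed males, by between −0.37 and −1.55. The families are parts of the same sets, and no family alone had an exact permutation p below 0.05 (0.0606 to 0.667).

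Class shares. Endothelial cells made up 5.93 ± 1.66% (SD, n = 6) of the cells of stressed males and 11.9 ± 4.96% (SD, n = 5) of control males, lower in 6 of 6 sets than the control mean (exact permutation p = 0.0216, adjusted p = 0.152). Oligodendrocytes made up 41.7 ± 15.9% and 30.8 ± 14.5% (adjusted p = 0.447 by exact permutation), neurons 26.2 ± 11.6% and 35.5 ± 8.23% (adjusted p = 0.384), and astrocytes 11.2 ± 5.27% and 7.28 ± 1.97% (adjusted p = 0.384). Ependymal cells, vsm cells and microglia stood at 10.7%, 2.68% and 1.59% in stressed and 9.79%, 2.41% and 2.26% in control males. No class passed the adjusted threshold, and 1 passed unadjusted. Within the shared lot the endothelial share was higher in stressed than in control males, by 2.44 percentage points. Shares also depend on dissociation and on the size range that a chip captures. Between control females and control males the exact adjusted p was 0.991 for all 7 classes, with endothelial cells at 7.09 ± 5.73% and 11.9 ± 4.96% (exact permutation, unadjusted p = 0.169, the lowest of the 7).

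**Figure D3:**
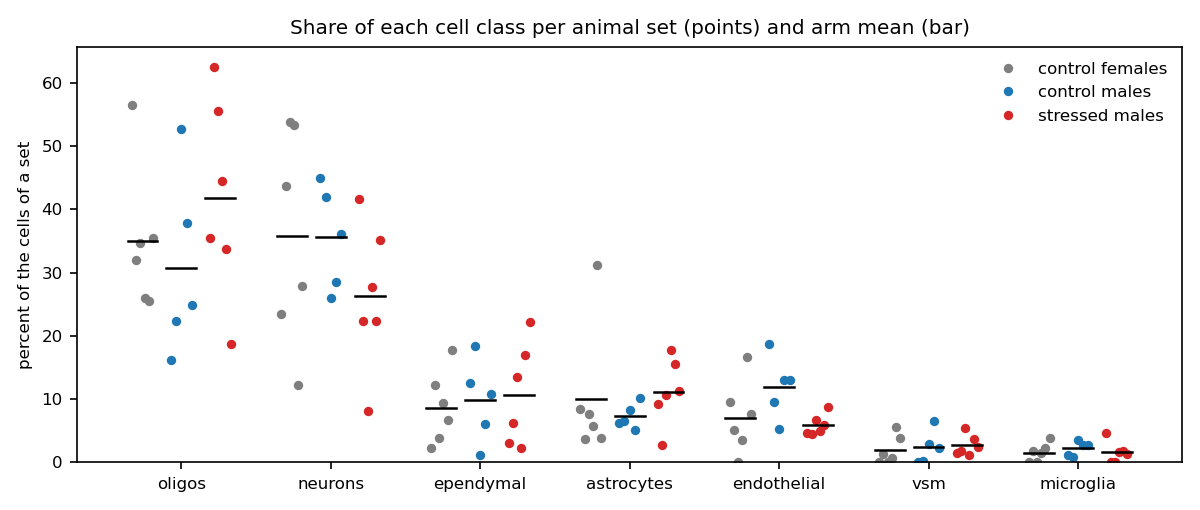
Percent of the cells of each animal set (vertical axis) that fell in each of the 7 classes (horizontal axis). Points are sets, coloured by arm, and bars are arm means. The endothelial share averaged 5.93% in stressed and 11.9% in control males.

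Molecules per cell and cell size. Median molecules per cell were lower in stressed than in control males in oligodendrocytes (log2 difference −0.37, 5 of 6 sets, exact permutation p = 0.0823) and neurons (−0.26, 6 of 6 sets, p = 0.108 by exact permutation). They stood at −0.30 in ependymal cells, 0.31 in astrocytes and 0.21 in endothelial cells. No class passed after adjustment (0 of 5 by the exact test, 0 unadjusted), with adjusted p between 0.271 and 0.563. Within the shared lot the difference in neurons was 0.07. Diameters did not differ detectably: the difference was −0.16 in oligodendrocytes, 0.18 in neurons, −0.53 in ependymal cells, −0.38 in astrocytes and −0.72 in endothelial cells, with exact adjusted p of 0.476 throughout.

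Sex. The comparison of control females with control males separated the sexes by the X-inactivation transcripts and Y-linked genes in all 5 classes. Xist (X chromosome, 103460366 to 103483254), the RNA that silences 1 X in females, stood at 698 ± 177 CPM (SD, n = 6) in female neurons. Control males had 0 counts among 4525883 molecules, which allows up to 0.663 CPM. In the pooled counts of female neurons, at 618 CPM, Xist was thus at least 933-fold higher. In oligodendrocytes Xist stood at 1100 ± 251 CPM (SD, n = 6) with 0 counts in control males, and at 1075 CPM in pooled counts, at least 1110-fold higher. Xist was also higher in female ependymal cells (714 ± 161 CPM, n = 4), astrocytes (1761 ± 587 CPM, n = 4) and endothelial cells (1780 ± 661 CPM, n = 5), with adjusted p of 1.09e-08, 5.75e-08 and 2.16e-09 in edgeR. Its antisense partner Tsix was higher in females in the 4 classes where it was tested, which leave out ependymal cells. The 2 genes overlap, and without the strand of the counting, which is not given, their molecules cannot be told apart. The RNA helicase gene Ddx3y (Y chromosome, 1260771 to 1286629) was lower in females in all 5 classes, at 4.00 ± 5.25 against 217 ± 47.4 CPM in neurons and 3.55 ± 5.16 against 280.0 ± 20.0 CPM in oligodendrocytes. Eif2s3y, a translation initiation factor gene, was also called in oligodendrocytes, neurons and astrocytes, and Uty and Kdm5d in oligodendrocytes and neurons.

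Apart from these, 3 genes were called by sex. Birc2, an inhibitor of apoptosis (chromosome 9, 7818227 to 7837064), was higher in females in oligodendrocytes (244 ± 46.7 against 117 ± 36.2 CPM, log2 fold change 1.04, SE 0.21, adjusted p = 0.0272, 6 of 6 sets) and in astrocytes (240 ± 155 against 36.7 ± 33.0 CPM, 3.13, SE 0.61, adjusted p = 0.00905, 4 of 4 sets). Gfap was higher in female astrocytes (745 ± 423 against 120 ± 67.3 CPM, 2.78, SE 0.49, adjusted p = 0.00352, 4 of 4 sets). Aqp4, the astrocyte water channel gene (chromosome 18, 15389496 to 15410982), was lower in female oligodendrocytes (4.46 ± 4.10 against 28.6 ± 7.66 CPM, −2.44, SE 0.49, adjusted p = 0.0272, 6 of 6 sets). With chip lot as a block Birc2 and Aqp4 in oligodendrocytes and Gfap and Birc2 in astrocytes were not called. In all edgeR called 8 of 7073 genes in oligodendrocytes, 6 of 7722 in neurons, 2 of 4516 in ependymal cells, 6 of 2534 in astrocytes and 3 of 2681 in endothelial cells. Of the 69 pairs of list and class 12 passed by sex with the preset correlation, and 0 with an estimated one. Astrocyte markers were lower in female oligodendrocytes (7 of 7 negative, mean −1.07, adjusted p = 1.66e-06, and 0.375 with an estimated correlation) and neurons (7 of 7, mean −0.69, adjusted p = 0.000172, and 0.463 with an estimated correlation). Immediate early genes were lower in female oligodendrocytes (16 of 16 negative, mean −0.64, adjusted p = 6.24e-05, and 0.899 with an estimated correlation), ependymal cells (−0.70) and neurons (−0.31), so control males stood highest of the 3 arms in neurons. In female ependymal cells neuron markers (−0.63, 9 of 10 negative, adjusted p = 0.000822) and astrocyte markers (−0.80) were lower too, and ependymal markers (0.49) and oligodendrocyte markers (0.62) higher. In female neurons oligodendrocyte markers (−0.31) and neuropeptide genes (−0.31) were lower. X-linked genes known to escape inactivation were higher in female oligodendrocytes (5 of 5 positive, mean 0.54, adjusted p = 0.000871, and 0.141 with an estimated correlation).

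Neuron families. The authors' neuron types were gathered into families by their names, and receptors and transcription factors outside those names were compared between a family and the other classified neurons of the same sets. The types were defined on the same cells, so these values describe the families and are not an independent test of them. Neurons named for oxytocin or vasopressin (45 cells, 6 sets) had less Nr3c1, the glucocorticoid receptor gene (chromosome 18, 39410545 to 39519421), at 46.3 ± 28.6 CPM (SD, n = 6) against 167 ± 16.5 CPM in other neurons (log2 fold change −1.67, SE 0.30, adjusted p = 0.000143 in edgeR, lower in 6 of 6 sets). The same neurons had more of the homeobox gene Pou3f2 (301 ± 140 against 37.1 ± 9.86 CPM, higher in 6 of 6 sets), Sim1 (116 ± 62.8 against 24.9 ± 10.1 CPM, 2.25, SE 0.38) and Foxp2 (135 ± 47.3 against 38.8 ± 10.5 CPM, 1.86, SE 0.30). They had less Isl1 (0.870 ± 2.13 against 87.4 ± 43.1 CPM) and Dlx1 (13.3 ± 17.0 against 78.1 ± 19.4 CPM). GABA neurons (192 cells, 15 sets) had more of the prolactin receptor gene Prlr (252 ± 118 against 108 ± 40.0 CPM, 1.11, SE 0.16, 14 of 15 sets), Dlx1 (1.54, SE 0.19), Isl1 (1.24, SE 0.22) and Zfhx3 (0.76, SE 0.11). Dopamine or Th neurons (31 cells, 7 sets) had more Npy2r, a neuropeptide Y receptor gene (125 ± 52.6 against 54.4 ± 24.2 CPM, 1.46, SE 0.33), and Dlx1 (1.62, SE 0.26). Suprachiasmatic neurons (55 cells, 10 sets) had more Rorb, a retinoid-related orphan receptor gene of the circadian clock (310 ± 270.2 against 129 ± 33.2 CPM, 1.17, SE 0.30, adjusted p = 0.0350 in edgeR, 7 of 10 sets). Glutamate neurons without a nucleus in their name (53 cells, 9 sets) had more Zfhx3 (0.66, SE 0.19). In that family edgeR called 904 of 2556 genes tested, so the call of 1 of 2 tested transcription factors does not set Zfhx3 apart. No gene of either list passed in arcuate or ventromedial neurons, where edgeR called 12 genes each over all genes tested. At an adjusted threshold over the list alone, Nr3c1 was higher in ventromedial neurons (0.65, SE 0.20, 12 of 14 sets).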

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

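Of the tests in this part, those on chip lot, on age and on oligodendrocyte RNA in the neurons, the set scores adjusted for lot or age, and the choice of the 3 patterns weighed, came after the values were seen. Counts of splits include the real grouping of the sets.

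Immediate early genes were lower in neurons of stressed males (mean log2 fold change −0.85, all 17 genes). In neurons with little oligodendrocyte RNA the mean was −0.73, which argues against RNA from oligodendrocytes as the cause. With chip lot as a block the mean was −0.65 (adjusted p = 1.10e-06) and the difference of set scores −0.60 (SE 0.18, mixed model, p = 0.00652), and in the shared lot the mean was −0.50 (adjusted p = 9.02e-05). These values argue against chip lot as the whole cause, though not against a part, and only 2 control male sets are in the shared lot. The set of day 23, held by that lot alone, had the lowest score of the control males (5.94). It lay below the stressed sets of days 28 and 29 (6.03 and 6.02). A different mix of neuron types stays open. The difference of summed levels was −0.78 over all neurons (exact permutation p = 0.0173) and −0.67 with neuron family held fixed (exact permutation p = 0.0649), so most of it stayed. But the second value misses the p of 0.05 set beforehand. All 8 families lay lower in stressed males, but they are parts of the same sets and not separate observations. Taken alone they had exact permutation p from 0.0606 to 0.667. In the GABA family the summed level differed by −0.38, and the list mean was −0.13. Lower neuronal activity 6 hours after the stress is an untested explanation. The list is not particular to neurons here: in control males the set scores averaged 6.52 in neurons, 6.72 in oligodendrocytes and 8.06 in astrocytes. They averaged 8.36 in ependymal cells and 9.43 in endothelial cells, each over the members tested in that class. The level of the list thus need not follow neuronal activity alone. Outside neurons the set scores differed by −0.55 in ependymal cells, −0.51 in endothelial cells, −0.23 in oligodendrocytes and 0.07 in astrocytes (exact permutation p from 0.230 to 0.865). Control males lay above control females too. Against those females the list mean in neurons was still −0.54 (camera, adjusted p = 0.000335). This argues against a high level in control males as the whole cause, though that comparison crosses stress with sex.

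Oligodendrocyte markers were higher in neurons of stressed males (mean 1.25, all 12 genes, adjusted p = 0.550 with an estimated correlation). If this is RNA released by oligodendrocytes, other oligodendrocyte genes should rise too, and 100 others had a median log2 fold change of 0.64, with 95 of 100 positive. They would also rise with neurons captured together with an oligodendrocyte or with chip lot, so this cannot tell release from either. The 100 genes come from the same sets and are not separate support. Whether a few neurons were captured together with an oligodendrocyte stays open: the set medians differed by 1.11 on the log2 scale with an exact permutation p of 0.169. Chip lot stays open as well. The control sets held by the shared lot alone, of day 23 in males and day 19 in females, had the highest scores of their arms (7.88 and 7.76). These values go with chip lot, and all 6 stressed sets have cells in that lot. The list passed in the shared lot (mean 1.20, adjusted p = 5.89e-06) and with lot as a block (0.93, adjusted p = 0.000942), but the sets vary too much to decide: the difference of set scores was within its spread both without lot (1.20, SE 0.68, p = 0.0984) and with lot as a block (1.18, SE 0.79, mixed model, p = 0.159). No biological explanation was tested.

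Glucocorticoid-responsive genes had a positive mean in stressed males in oligodendrocytes, neurons and astrocytes (0.38, 0.42 and 0.60), with all 3 calls lost with an estimated correlation (adjusted p = 0.298, 0.457 and 0.153). The mean was 0.24 in ependymal cells (adjusted p = 0.0816) and −0.11 in endothelial cells (adjusted p = 0.503). Without the stressed set of day 25 or of day 28 the mean in oligodendrocytes was 0.23 or 0.24. Over the list alone Cdkn1a rose in oligodendrocytes and Fkbp5, Mt1 and Mt2 in neurons. A rise in corticosterone, which was not measured, stays an untested explanation. In the shared lot, with 2 control male sets, the means were 0.43, 0.62 and 0.79. With lot as a block they were 0.26 (adjusted p = 0.0627), 0.54 (0.000249) and 0.86 (0.00820), so the call ended in oligodendrocytes and stayed in neurons and astrocytes. The differences of set scores were 0.39 (SE 0.15, p = 0.0200), 0.32 (SE 0.25, p = 0.217) and 0.75 (SE 0.26, p = 0.0131) in linear models without lot. With lot as a block they were 0.38 (SE 0.17, p = 0.0443), 0.52 (SE 0.26, p = 0.0694) and 0.50 (SE 0.31, p = 0.144) in mixed models. Chip lot and stress cannot be told apart: in oligodendrocytes the list call ended, in astrocytes the difference of scores fell within its spread, and in neurons the scores were within their spread without lot too and so cannot decide, although the list mean did not shrink. With age as a covariate the call ended in oligodendrocytes (0.28, adjusted p = 0.0715) and stayed in neurons (0.60, 6.81e-05) and astrocytes (0.54, 0.00700). The differences of set scores with age were 0.25 (SE 0.14, p = 0.0869), 0.48 (SE 0.26, p = 0.0844) and 0.58 (SE 0.27, p = 0.0597) in linear models. Age stays open in oligodendrocytes and astrocytes, where these differences shrank, and in neurons, where they grew but the scores were within their spread without age too and so cannot decide. In neurons with little oligodendrocyte RNA the mean was 0.31 (adjusted p = 0.0827), so that RNA stays open too.

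The numbers of genes were compared with other splits of the same sets. Adjusted stress counts were 0 in edgeR, so genes at an unadjusted p below 0.05 were counted. In oligodendrocytes 4 of 100 splits were as large (429 genes against at most 541 in another split), and in ependymal cells 1 of 35 (454 against 361). Each class taken alone lies under the 5% of splits set beforehand, but chance cannot be excluded once the 5 classes compared are allowed for. The split with 541 genes partly follows chip lot, since the 3 male sets held by the shared lot alone are on one side. With lot as a block the count was 180 in oligodendrocytes and 129 in ependymal cells. Both are below 5% of the 7073 and 4516 genes tested without that block, though the fit with the block has its own units and filter. Only 1 lot holds both kinds of male, so the block can also remove an effect of stress. These counts therefore cannot tell lot, stress and chance apart. In neurons (10 of 100, 519 against 895), astrocytes (21 of 100, 104 against 316) and endothelial cells (18 of 100, 111 against 207) chance cannot be excluded for a class taken alone either. For the genes called by sex, as many were called in 3 of 100 splits in neurons (6 genes against 82), 1 of 100 in astrocytes (6 against 4), 2 of 100 in endothelial cells (3 against 3), 7 of 100 in oligodendrocytes (8 against 378) and 2 of 35 in ependymal cells (2 against 5). The genes called in neurons, endothelial cells and ependymal cells were Xist, Tsix and Y-linked genes without exception, as were 4 of the 6 in astrocytes. The sex of the sets fixes these, so the splits say nothing about chance there, and in oligodendrocytes chance cannot be excluded for the number of genes. The split with 378 genes in oligodendrocytes largely follows chip lot and points to a structure of the sets, and with lot as a block 6 genes were called. Nor can chance be excluded for the 18 pairs of list and class under stress (17 of 100 splits, highest other 23) or the 1 interaction gene (11 of 100, highest other 6). For the 7 neuron families 1 split, the real one, was as large, which says nothing about chance because the types were made from the expression of the same cells: arcuate (of 64, 12 genes against 10), dopamine or Th (of 64, 40 against 6), GABA (of 100, 212 against 60), oxytocin or vasopressin (of 32, 648 against 132), suprachiasmatic (of 100, 29 against 1), other glutamate (of 100, 904 against 67) and ventromedial (of 100, 12 against 3).

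The stress effect on Arc differed between classes by a test of the interaction (adjusted p = 0.0427). With RLE scaling, and without any 1 of 8 of the 11 male sets, 0 genes passed that test. Among 45 groups of sets examined, of which chance gives 1 in 20, 5 held a set far from the others. Astrocytes made up 31.1% of the cells of the control female set of day 28 (next 8.38%), and oligodendrocytes 56.4% of the control female set of day 19 (next 35.4%). The latter is the only control female set in the shared lot. The control male set of day 23, held by that lot alone, had the highest oligodendrocyte share of its arm (52.7%). The mean log2 CPM of glucocorticoid-responsive genes was 8.85 in astrocytes of the control female set of day 28 (next 8.49) and 6.73 in oligodendrocytes of the control female set of day 29 (next 6.36). Median molecules per cell were 10550 in the control male set of day 21 (next 7517). The chip of 83 control cells without a sex label entered no comparison and held 267 CPM of Y-linked transcripts and 0 of Xist, against at most 11.6 CPM of Y-linked transcripts in control female sets.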

How the results depend on the processing

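Chip lot as a block, control females as the reference, neurons with little oligodendrocyte RNA, neurons of the GABA family, neurons with an assigned type and the exact permutation of set scores were added after the values were seen. No paired analysis was possible because replicate numbers only count the animal sets and pair no animals. In ependymal cells, astrocytes and endothelial cells 2-fold changes were mostly missed in simulation, and whether depth, spread or the number of sets limits them was not tested. Except where a test's construction shows it, the cause of each difference was not tested. Leaving aside the sets left out in turn, 142 of the 195 alternative values that answer a comparison kept their direction and side of the threshold. The 7 pairs of list and class that follow kept their sign under all alternatives run, and their ranges leave aside the sets left out in turn. Immediate early genes in neurons came nearest 0 at −0.13 (adjusted p from 3.03e-15 to 0.747). The mean log2 fold change of glucocorticoid-responsive genes ranged from 0.26 to 0.46 in oligodendrocytes (0.000132 to 0.456), 0.30 to 0.62 in neurons (2.56e-06 to 0.469) and 0.44 to 0.86 in astrocytes (2.48e-06 to 0.456). Oligodendrocyte markers ranged from 0.93 to 1.56 in neurons (3.94e-11 to 0.550), and neuron markers in ependymal cells from −1.95 to −0.52 (3.94e-11 to 0.550). In ependymal cells oligodendrocyte markers ranged from 0.70 to 4.80, with adjusted p of up to 0.693. The 4.80 is from the shared lot, where only 1 control male set had enough ependymal cells.

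Against 0 genes under stress in edgeR (unadjusted counts of 104 to 519 per class), DESeq2 called 10 in neurons, 1 in ependymal cells (Malat1) and 1 in endothelial cells (Abr). With age as a covariate 83 were called in neurons, and with male sets only 18 in neurons and 7 in ependymal cells. The chip as the unit gave 14 in oligodendrocytes, 25 in neurons and 1 in ependymal cells (Gapdh), and treats chips of 1 set as separate. Without a filter on low counts there were 1 in oligodendrocytes (Caly), 8 in neurons, 44 in ependymal cells, 3 in astrocytes (Cenpf, Pdgfra, Top2a) and 1 in endothelial cells (Hdc). Against control females, which crosses stress with sex, there were 8 in oligodendrocytes, 10 in neurons, 2 in ependymal cells (Ddx3y, Xist), 5 in astrocytes (Ddx3y, Eif2s3y, Mfsd2a, Tsix, Xist) and 3 in endothelial cells (Ddx3y, Tsix, Xist). No count is given for ependymal cells in the shared lot, where only 1 control male set had enough of them. Chip lot as a block gave 1 in neurons (Kitl) and the GABA family 1 (Ptgds). These genes were chosen after their values were seen. Genes called by sex went from 6 to 2 in astrocytes with lot as a block (Ddx3y, Xist), and without a filter from 2 to 16 in ependymal cells and from 3 to 8 in endothelial cells. The interaction gave 0 genes with RLE scaling, 2 in oligodendrocytes and neurons alone and 122 without a filter, against 1. Lists past the threshold went from 18 to 1 with an estimated correlation and to 30 without a filter, and class shares from 0 to 2 with the chip as the unit.

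With an estimated correlation the calls ended at unchanged means for glucocorticoid-responsive genes in oligodendrocytes (0.38, adjusted p = 0.298), neurons (0.42, 0.457) and astrocytes (0.60, 0.153), oligodendrocyte markers in neurons (1.25, 0.550) and ependymal cells (1.45, 0.564) and neuron markers in ependymal cells (−1.65, 0.550). By exact permutation of set scores these calls (0.39, 0.36, 0.68, 1.24, 1.01 and −1.95) and that of immediate early genes in neurons (−0.85) did not pass (adjusted p from 0.456 to 0.693). The adjusted p says nothing about their stability: the smallest p possible is 0.00433 with 6 against 5 sets and 0.0286 with 4 against 4, so 1 pair alone could not pass when adjusted over 69. Unadjusted, the exact permutation p was 0.0216, 0.0476, 0.0159, 0.0390, 0.371 and 0.0286 in the same order, and 0.0130 for immediate early genes in neurons. Oligodendrocyte markers in ependymal cells, at 0.371, were thus within the spread between sets. Calls also ended for glucocorticoid-responsive genes in oligodendrocytes with age (0.28, adjusted p = 0.0715) and lot as a block (0.26, 0.0627), in neurons with little oligodendrocyte RNA (0.31, 0.0827) and in the GABA family (0.37, 0.449), and in astrocytes in the shared lot (0.79, 0.0690), where fewer sets are compared. They ended for immediate early genes in the GABA family (−0.13, 0.747), neuron markers in ependymal cells with lot as a block (−0.52, 0.0571) and against females (−1.02, 0.305), and oligodendrocyte markers in ependymal cells with the chip as the unit (0.70, 0.142).

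Directions reversed as follows. Against females: immediate early genes in oligodendrocytes 0.16, ependymal markers in ependymal cells −0.0213, Fos in oligodendrocytes 0.0981 and astrocytes 0.70, Oxt in neurons −0.47. With age: Oxt in oligodendrocytes 4.63 and neurons −1.29, Avp in astrocytes 2.03. With lot as a block: oxidative phosphorylation genes in astrocytes 0.21, immediate early genes in endothelial cells 0.16, Avp in oligodendrocytes 0.00612, Oxt in oligodendrocytes 3.29, Fos in ependymal cells 0.21 and endothelial cells 0.0378, Sgk1 in endothelial cells 0.77. In the shared lot: stress axis genes in oligodendrocytes 0.20, oxidative phosphorylation genes in astrocytes 0.33, Avp in oligodendrocytes 1.97 and astrocytes 5.07, Oxt in oligodendrocytes 2.75, Fos in ependymal cells 0.44 (1 control male set), Sgk1 in endothelial cells 0.79, ependymal share −7.86, endothelial share 2.44, log2 molecules in neurons 0.0745. With the chip as the unit: Avp in neurons 0.79, Tsc22d3 in endothelial cells 0.34, neuron share by sex −2.25, log2 molecules in endothelial cells −0.34. With at least 3000 molecules per cell: ependymal share −0.310, microglia share 0.344, and by sex neuron share −0.334 and microglia share 0.524. With little oligodendrocyte RNA: Tsc22d3 −0.40 and Avp 0.34 in neurons. In the GABA family: cholesterol synthesis genes −0.0725 and Avp 1.81. Without uc neurons Avp in neurons was 0.15, with 10 cells per set Tsc22d3 in endothelial cells 0.0979, and with neurons left out of the total the ependymal share −1.76. Among neurons with an assigned type the suprachiasmatic share was 0.780 higher.

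With 1 set left out at a time, these 7 pairs kept their calls. Glucocorticoid-responsive genes ranged from 0.23 to 0.50 in oligodendrocytes (0.23 without the stressed set of day 25, 0.24 without that of day 28), 0.34 to 0.49 in neurons and 0.49 to 0.69 in astrocytes. Immediate early genes in neurons ranged from −0.96 to −0.77, oligodendrocyte markers from 0.98 to 1.54 in neurons and 0.97 to 1.82 in ependymal cells, and neuron markers in ependymal cells from −2.31 to −1.34. Stress genes ranged from 0 to 3 in oligodendrocytes (Chd8, Lars2, Wipi1) and from 0 to 6 in neurons (Arc, Btg2, Egr4, Fos, Gad2, Npas4), both highest without the control male set of day 23. The interaction ranged from 0 to 2 genes, at 0 without the control male sets of days 16, 21 or 25 or the stressed sets of days 24, 25, 27, 28 or 29. Classes past the threshold for molecules per cell ranged from 0 to 1, at 1 without the control male set of day 23 or the stressed set of day 25. Ranges that crossed 0 were −2.37 to 2.93 for Oxt in oligodendrocytes, −0.82 to 0.80 for Avp and −0.30 to 1.73 for Oxt in neurons, −0.34 to 0.0659 for Tsc22d3 in endothelial cells, −1.39 to 3.07 for the ependymal share and −0.338 to 1.30 for the vsm share under stress. By sex they were −0.101 to 9.66 for the oligodendrocyte share, −3.45 to 4.88 for neurons, −3.27 to 1.05 for ependymal cells, −1.40 to 4.07 for astrocytes and −1.23 to 0.534 for vsm cells.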

Other observations

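Avp and Oxt, whose RNA fills the secretory neurons of the hypothalamus, were counted outside neurons too. In oligodendrocytes of control males Avp stood at 528 ± 585 CPM and Oxt at 1868 ± 3748 CPM (SD, n = 5 sets), and 1 set, of day 16, held 8546 CPM of Oxt while the other 4 held at most 779. In oligodendrocytes of stressed males 1 set too, of day 29, held 7352 CPM of Oxt while the other 5 held at most 923. In astrocytes Oxt stood at 846 ± 1400 CPM (SD, n = 5) in stressed males, with 3283 CPM in the set of day 28, 797 in that of day 22 and at most 72.1 in the other 3, and at 9.26 ± 15.1 CPM (SD, n = 5) in control males.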
